A study of Mus musculus with 6 samples.

How the data were processed

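Long non-coding RNA (lncRNA) was profiled in zygotes of C57BL/6 mice at the pronucleus stage, the interval after fertilisation in which the maternal and paternal genomes still lie in separate pronuclei. There were 6 libraries, 3 from zygotes under normal gravity (control) and 3 from zygotes under simulated microgravity. Groups and replicate numbers were taken from the sample titles. In the titles the 3 libraries of a group carry the same prefix before the replicate number. What that prefix marks is not given, so each group may come from a single set of zygotes. Per the labels' protocols, zygotes were frozen and collected in lysis buffer, and libraries were built from single-cell cDNA by a standard Illumina protocol. The device that simulated microgravity, the length of exposure and the number of zygotes per library are not given in the sources used here. The labels do not say whether the 3 libraries of a group came from separate pools of embryos, so p-values measure only the spread between these libraries, which may be partly technical.

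Per the file headers, the deposited values are RPKM (reads scaled by transcript length and library size), with 1 value per lncRNA locus and library. The authors gave each locus an assembly identifier and its coordinates. The genome build was mm9, per the submitters' processing notes. The coordinates reached 151211286 on chromosome 7 and 131183679 on chromosome 8. The aligner, the assembler, the counting method and the rule by which loci were called non-coding are not given in the sources used here. Neither is the set of reads to which values were scaled, nor whether counting used strand. The 6 tables held the same 3307 loci in the same order, and no value above 0 was shared by any 2 libraries at the same locus. Traces of whole reads were searched for in the ratios between 2 libraries at loci under 200 RPKM, which should gather at 1 constant times fractions of small whole numbers (up to 6). In 4 of the 15 pairs such a comb was found (peak at least 6.41 standard deviations, against at most 4.26 in the other pairs). There 1 read was worth 0.992 times as much RPKM in microgravity replicates 1 and 3 as in control replicate 2, 0.999 times as much in microgravity replicate 3 as in microgravity replicate 1, and 1.01 times as much in microgravity replicate 2 as in control replicate 3. Only these relative steps could be had. The search covered a limited range of ratios around 1, so larger differences would have gone unseen. The number of reads per library is unknown, reads per locus could not be recovered for the table as a whole, and no counting interval is given. RPKM is a relative measure: a locus that takes a larger part of a library lowers the value of every other locus.

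The tables do not pair the loci with gene names. The annotation at hand was of the GRCm38 build, and coordinates were not converted between builds, so no locus was given a gene name, exon structure or strand. The 15 gene lists fixed beforehand (imprinted, X-inactivation, snoRNA host, microRNA host, structural, stress, pluripotency and homeobox lncRNAs; oocyte, genome activation, cytoskeleton and oxidative stress genes; and cumulus, sperm and blood markers) matched 0 of the loci and were not tested. Presence of RNA from cumulus cells, sperm or blood, or of ribosomal RNA among the listed loci, was therefore not examined. A total of 145 sets of coordinates were listed for more than 1 locus, covering 297 loci. How reads were divided between such loci is not given in the sources used here.

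Microgravity was compared with control with limma 3.58.1 in R 4.3.3, on log2(RPKM + 1), with a mean-variance trend, robust moderation and no other covariate. Loci with at least 1 RPKM in at least 3 libraries were tested, which left out 6 of the 3307. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates the change of loci at low levels. Chromosomes were tested as sets of loci with camera (preset inter-gene correlation of 0.01, and again with an estimated correlation) and with fry, both from limma. Measures with 1 value per library were compared by an exact two-sided permutation test of the difference of means, which with 3 against 3 libraries cannot give a p below 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

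The model was tested on simulated data before use. Each of 20 simulations drew values for the 3301 tested loci from their own mean and moderated standard deviation and changed 200 of them, in equal parts by 2, 4, 8 or 16-fold. The test recovered 44.3% of 2-fold, 82.1% of 4-fold, 91.5% of 8-fold and 97.3% of 16-fold changes, and 6.09% of its calls were false. Simulated loci varied independently. With fewer changed loci the adjusted threshold would be harder to reach, and this was not simulated. The shares recovered therefore do not show how large a change the real comparison could have missed.

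The test of the loci, its alternatives, camera on chromosomes and the rule for the loci described individually were set before the data were examined. The fry tests on chromosomes were not. The rule took the 10 loci with the largest fold change in each direction among those past the adjusted threshold. Where fewer passed, it filled each direction up to 10 by the smallest unadjusted p, as values only. It added the 5 loci with the highest mean level, and members of the gene lists, of which there were none. Alternatives were the replicate number as a block, leaving out each library, quantile normalization, median scaling, no filter or at least 5 RPKM on low values, limma without trend and robust moderation, pseudocounts of 0.1 and 0.5, library weights, and thresholds on unadjusted p and fold. Scaling without the most abundant locus was chosen after seeing the data.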

Results

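The lncRNA content of mouse zygotes at the pronucleus stage was measured by RNA sequencing in 3 libraries under normal gravity and 3 under simulated microgravity. The tables listed 3307 lncRNA loci on 20 chromosomes (the 19 autosomes and X), with a median genomic span of 10590 bp and a range from 402 to 657549 bp. RPKM values summed to between 892582 and 928980 per library, with medians from 70.4 to 74.7 RPKM. The number of reads per library is unknown. The RPKM value of 1 read could be compared in 4 of the 15 pairs of libraries. None of them held control replicate 1 or joined 2 control libraries. Across the groups the ratio was 0.992 between either of microgravity replicates 1 and 3 and control replicate 2. It was 1.01 between microgravity replicate 2 and control replicate 3. How depth compared in the other pairs is unknown.

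The 2 groups had the same mean number of loci above 0, but the list left little room for a difference. Of the listed loci, 0 were at 0 in every library, and only 22 to 49 were at 0 in a given library. The counts therefore say little about detection. A mean of 3272 ± 13.5 loci (SD, n = 3) was above 0 in control and of 3272 ± 8.08 (SD, n = 3) in microgravity, and 3161 loci (95.6%) were above 0 in all 6 libraries. The 10 most abundant loci held 15.9% ± 0.532 (SD, n = 3) of the summed RPKM in control and 16.3% ± 0.933 (SD, n = 3) in microgravity (exact permutation test, two-sided, p = 0.6; the smallest p the design allows is 0.1). Without microgravity replicate 2 this difference was -0.0751 percentage points, against 0.451 with it. The similarity of libraries overlapped within and across groups. Pearson's r of log2(RPKM + 1) across loci, which are not independent replicates, ran from 0.881 to 0.885 among control pairs, from 0.867 to 0.886 among microgravity pairs and from 0.842 to 0.891 between the groups. Microgravity replicate 2 had the lowest r with each control library (0.842 to 0.866) and the lower values among microgravity pairs (0.867 and 0.878), and the lowest weight of the 6 when limma weighted libraries (0.772, against 0.908 to 1.21).

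The 5 most abundant loci had similar values in both groups. The most abundant lay on chromosome 17 (39982698 to 39985516, mm9) and had a mean of 33055 ± 4946 RPKM (SD, n = 3) in control and 40306 ± 11441 (SD, n = 3) in microgravity, where replicate 2 alone reached 53489 RPKM. That locus took from 3.09% to 5.99% of the summed RPKM of a library, the highest share being in microgravity replicate 2. What RNA it holds was not examined, so whether this share is lncRNA or ribosomal RNA is unknown. A locus on chromosome 7 (54222161 to 54243580) had 21742 ± 1079 RPKM (SD, n = 3) in control and 20324 ± 2906 (SD, n = 3) in microgravity. On chromosome 6, the locus from 89125622 to 89162622 had 19420 and 18466 RPKM and the locus from 10921481 to 10929750 had 15351 and 15469 RPKM, in control and microgravity respectively. The fifth, on chromosome 1 (64726494 to 64737441), had 11118 RPKM in control and 11493 RPKM in microgravity. None of the 5 passed the test (limma, lowest adjusted p = 0.685), and their log2 differences lay between -0.11 and 0.26. Among them, the loci on chromosome 7 and at 10921481 on chromosome 6 shared their coordinates with 1 other listed locus each.

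The study's question was whether lncRNA expression at this stage differs between normal gravity and simulated microgravity. No lncRNA locus passed the adjusted threshold: of 3301 loci tested, 0 were called higher and 0 lower in microgravity (limma, lowest adjusted p = 0.327). At an unadjusted p under 0.05, 261 loci (7.91%) differed, where 165 would be reached by chance alone, and limma without trend and robust moderation gave 0 calls and 246 such loci. Of the 261, 159 had higher and 102 lower values in microgravity, a split that was 139 and 134 after median scaling. With a 2-fold minimum added, 90 loci remained at unadjusted p under 0.05, 55 higher and 35 lower. Leaving out control replicate 1 gave 1 call, XLOC_001319 on chromosome 1. Without microgravity replicate 2, 0 loci were called and 210 were at unadjusted p under 0.05. Leaving out microgravity replicate 1 took the lower loci to 158 at unadjusted p under 0.05 and to 57 with the 2-fold minimum. The loci with the 2-fold minimum came to 53 lower ones without microgravity replicate 3 and 85 higher ones without control replicate 3.

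For most lncRNA loci at high levels, a difference of 2-fold or more lay outside the confidence interval. The 95% confidence interval lay within 2-fold in both directions for 1583 loci (48.0%), and within 1.5-fold for 457 (13.8%). Each interval holds for a single locus and was not adjusted over loci. Like the p-values, it rests on the spread between these libraries, so it does not bound the effect of microgravity itself. Divided into tertiles by mean level, the interval lay within 2-fold for 994 of 1100 loci in the highest tertile (median 306 RPKM), for 531 of 1100 in the middle (median 73.0 RPKM) and for 58 of 1101 in the lowest (median 27.9 RPKM). The median moderated standard deviation of limma on the log2 scale was 0.25, 0.41 and 0.72 in the same order. Moderation draws these values towards a trend with level, so part of this gradient may come from the model. Of the 90 loci at unadjusted p under 0.05 and at least 2-fold, 57 were in the lowest tertile, 32 in the middle and 1 in the highest. Without the 2-fold minimum the order was reversed, with 63 of 261 in the lowest, 88 in the middle and 110 in the highest. For loci at low levels, differences of 2-fold were thus mostly not detectable with this spread, and no statement of absence is made for them.

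**Figure D1:**
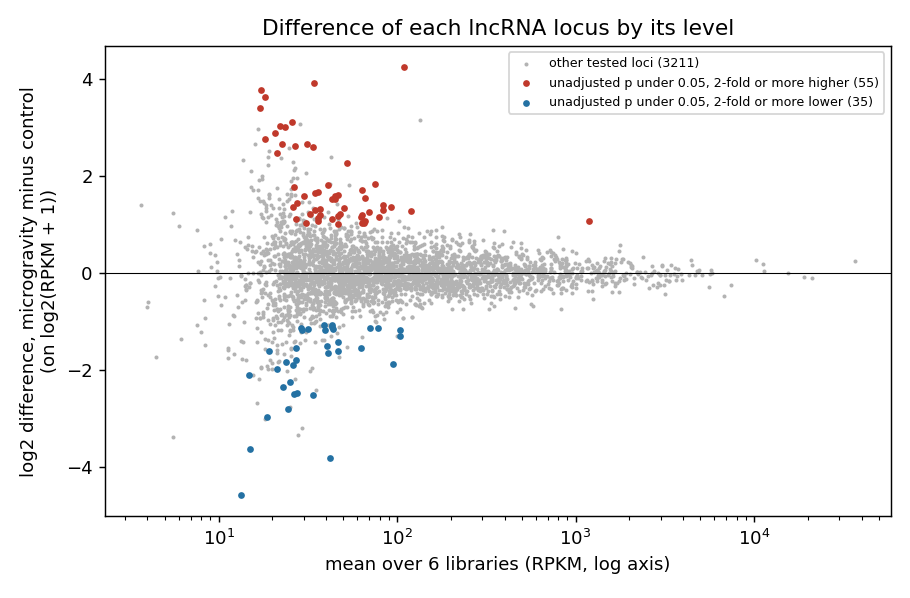
Log2 difference between microgravity and control (vertical axis, on log2(RPKM + 1)) against the mean RPKM over 6 libraries (horizontal log axis), 1 point per tested locus. The 55 higher (red) and 35 lower (blue) loci at unadjusted p under 0.05 and at least 2-fold lie mostly at low levels, 57 in the lowest tertile, 32 in the middle and 1, near 1187 RPKM, in the highest, and none passed the adjusted threshold.

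Among the loci with higher values in microgravity, the smallest p belonged to XLOC_001319 on chromosome 1 (168268693 to 168281540, mm9). Its values were 23.6, 4.80 and 3.41 RPKM in the control libraries and 166, 395 and 64.8 RPKM in the microgravity libraries, a log2 difference of 4.25 ± 0.73 (SE; limma, adjusted p = 0.327). This was the locus called when control replicate 1 was left out, with a log2 difference of 5.01 and an adjusted p of 0.0304. It was not called when any other library was left out: the log2 difference was 4.91 (limma, adjusted p = 0.166) without microgravity replicate 3, 3.97 (adjusted p = 0.607) without control replicate 2 and 3.61 (adjusted p = 0.607) without microgravity replicate 2. XLOC_004230 on chromosome 11 (13063302 to 13068239) had 32.9 ± 13.4 RPKM (SD, n = 3) in control and 117 ± 25.1 (SD, n = 3) in microgravity, a log2 difference of 1.85 ± 0.35 (SE; limma, adjusted p = 0.327). Other loci of this group, each with limma adjusted p values between 0.327 and 0.493, lay on chromosome 16 (13040469 to 13083434; 45.0 ± 2.45 RPKM in control and 123 ± 30.3 in microgravity), chromosome 2 (8378858 to 8379485; 281 ± 37.6 and 517 ± 85.3) and chromosome 17 (43277620 to 43292349; 51.9 ± 14.5 and 132 ± 12.4). A short locus on chromosome 1 (117283481 to 117284239) had 19.6 ± 11.5 RPKM in control and 86.0 ± 20.9 in microgravity. The only locus of the highest tertile at unadjusted p under 0.05 and at least 2-fold was on chromosome 11 (102277617 to 102278647). It was at 777 ± 263 RPKM in control and 1596 ± 403 in microgravity. The remaining 3 were on chromosome 3 (47444418 to 47460959; 122 ± 28.8 and 235 ± 34.2 RPKM), chromosome 16 (19065318 to 19198945; 1414 ± 163 and 2116 ± 301 RPKM, coordinates shared with 1 other locus) and chromosome 11 (62416257 to 62418312; 239 ± 30.8 and 454 ± 125 RPKM). Errors of RPKM values are SD over 3 libraries.

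Among the loci with lower values in microgravity, XLOC_010887 on chromosome 15 (93836647 to 93840555, mm9) had 146 ± 9.56 RPKM (SD, n = 3) in control and 43.3 ± 22.2 (SD, n = 3) in microgravity, a log2 difference of -1.88 ± 0.39 (SE; limma, adjusted p = 0.327). XLOC_017097 on chromosome 2 (123683086 to 123687272) had 108 ± 12.9 RPKM (SD, n = 3) in control and 48.7 ± 5.05 (SD, n = 3) in microgravity, a log2 difference of -1.13 ± 0.27 (SE; limma, adjusted p = 0.493). A locus on chromosome 4 (3314114 to 3316129) had 70.3, 58.4 and 99.5 RPKM in the control libraries and 14.4 and 9.10 RPKM in microgravity replicates 1 and 2, and was listed at 0 in replicate 3. The ninth most abundant locus of the table, on chromosome 7 (122091922 to 122127323), had 7842 ± 655 RPKM in control and 5686 ± 952 in microgravity, a log2 difference of -0.47 with a 95% interval from -0.74 to -0.20. Others lay on chromosome 17 (9475903 to 9562700; 706 ± 16.3 and 446 ± 100.1 RPKM), chromosome 5 (76929491 to 76931987; 92.9 ± 25.8 and 32.9 ± 16.9 RPKM) and chromosome 3 (138789547 to 138810569; 1030.0 ± 169 and 624 ± 153 RPKM). The last 3 lay on chromosome 1 (192253921 to 192270849; 1472 ± 131 and 1028 ± 136 RPKM, coordinates shared with 1 other locus), chromosome 11 (20045421 to 20053823; 99.6 ± 6.82 and 50.4 ± 9.75 RPKM) and chromosome X (87479609 to 87483316; 405 ± 53.7 and 246 ± 53.9 RPKM). The limma adjusted p values of these 10 loci lay between 0.327 and 0.498.

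**Figure D2:**
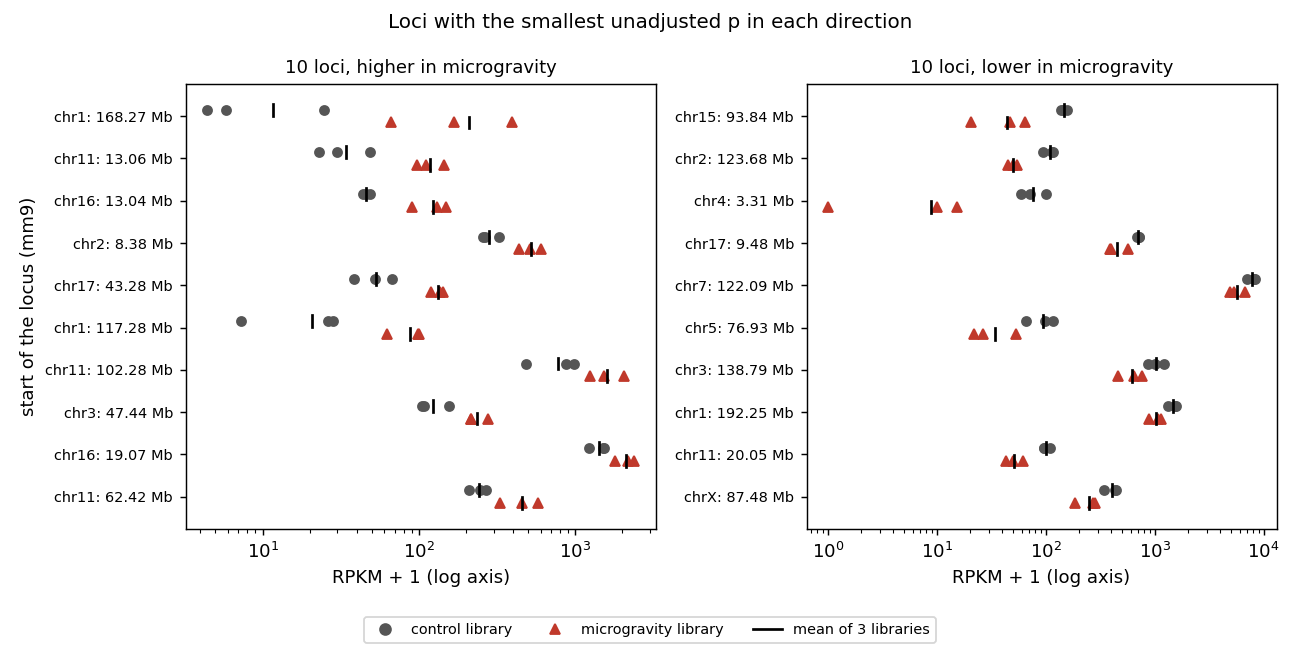
RPKM + 1 (log axis) in each library at the 10 loci with the smallest unadjusted p in each direction, labelled by chromosome and start in mm9; circles are control libraries, triangles microgravity libraries and bars the mean of 3. The 3 libraries of one group lie apart from the 3 of the other at all 20 loci, which a choice by smallest p favours. No adjusted p was under 0.327.

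At all 20 of these loci the 2 groups did not overlap, which a choice by smallest p in the same comparison favours. Over the 3301 loci tested this held for 450 (13.6%), where chance gives 10% with 3 against 3 libraries. It held for 244 loci with higher and 206 with lower values in microgravity, a majority that turned to 211 and 247 after median scaling and to 223 and 231 after quantile normalization.

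No chromosome was called as shifted as a whole. The median log2 difference per chromosome lay between -0.10 (chromosome 7, 122 loci) and 0.06 (chromosome 3, 207 loci), against -0.0037 over all loci, and was -0.01 on the X chromosome (108 loci). Camera called 0 of 20 chromosomes (lowest p = 0.121, lowest adjusted p = 0.947; none at an unadjusted p under 0.05), and 0 with an estimated correlation (lowest adjusted p = 0.975). On chromosomes 1, 12 and 13 the median and the direction given by camera had opposite signs. The fry test for a shift in one direction also called 0 (lowest adjusted p = 0.657). The fry test for change in either direction, which was not set beforehand and does not compare a chromosome with the others, called 5: chromosomes 3 and 6 (adjusted p = 0.0204 each), 14 and 17 (adjusted p = 0.0341 each) and 11 (adjusted p = 2.0e-05). With the replicate number as a block it called 2, chromosomes 11 (adjusted p = 0.00505) and 7, and the calls of 3, 6, 14 and 17 were lost. Chromosome 11 held 145 tested loci, of which 10 were higher and 5 lower in microgravity at unadjusted p under 0.05. The number of chromosomes called in this way depended on single libraries: it was 1 without control replicate 1, 1 without control replicate 2, 11 without control replicate 3, 13 without microgravity replicate 1, 4 without microgravity replicate 2 and 8 without microgravity replicate 3. Chromosome 11 was the only one called each time.

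**Figure D3:**
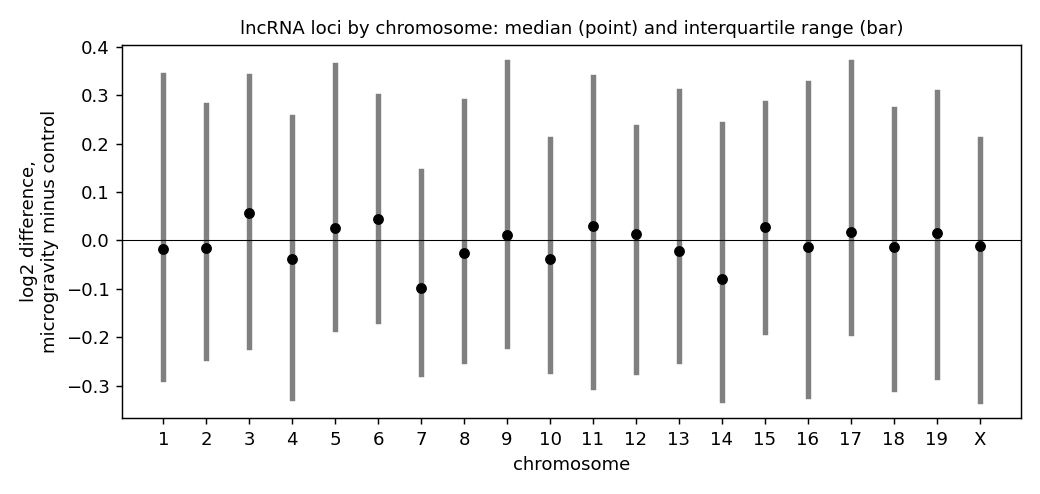
Median (point) and interquartile range (bar) over lncRNA loci of the log2 difference between microgravity and control, by chromosome (horizontal axis). All 20 medians lie between -0.10 and 0.06.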

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

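The scaling without the most abundant locus, and every alternative for the test of change in either direction, were chosen after seeing the data, and that test itself was not among those set beforehand. The count of 0 called loci held under all alternatives run except 2. It was 1 without control replicate 1 (0 to 1 over the 6 fits that left out a library). It was 90 when unadjusted p under 0.05 and 2-fold replaced the adjusted threshold. Some alternatives could hardly have moved it. With no filter 3307 loci were tested and with at least 5 RPKM 3294, against 3301. A 2-fold minimum added to the adjusted threshold could not have raised a count of 0. Loci at unadjusted p under 0.05 numbered 190 to 310 without single libraries and 243 to 274 otherwise, and those with at least 2-fold 88 to 118 and 73 to 95. Of the 90 such loci, between 47 and 65 were found again when a library was left out. The number of loci bounded within 2-fold was 1269 to 1421 without single libraries and 1515 to 1597 otherwise, and that of loci whose groups did not overlap 449 to 458. Chromosomes called for change in either direction, 5 in the report, were 1 to 13 without single libraries, 9 after quantile normalization, 8 with a pseudocount of 0.1, 8 with 0.5 and 2 with the replicate block, which ended the calls of chromosomes 3, 6, 14 and 17 and added chromosome 7 (the cause was not tested); with library weights this was not run. Camera called 0 chromosomes in every fit run. The difference in the share of the top 10 loci was 0.451 percentage points, -0.0751 to 0.814 without single libraries, and -0.0529 for the top 50; that in detected loci was -6.83 to 6.67. The 10 loci with the smallest p in each direction kept that direction under every alternative run. Their groups did not overlap, so leaving out a library could not have reversed it. Only the changes of normalization or scaling could have. Among the 5 most abundant, the log2 difference turned to 0.059 (89125622 on chromosome 6) and -0.094 (64726494 on chromosome 1) with quantile normalization, and at 10921481 on chromosome 6 to -0.021 with median scaling and to between -0.042 and 0.044 without single libraries. With the replicate number as a block there were 0 calls and 255 loci at unadjusted p under 0.05. Same-numbered libraries did not deviate together (correlations of 0.017, -0.0037 and -0.017), so the numbers were not taken as pairs, and not every library correlated best with its own number. The alternative settings listed for the gene lists were not run, since no list could be matched. Reads per library are unknown, so what counting error adds to the spread cannot be given.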

Other observations

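The tests on loci at unadjusted p under 0.05, with and without the 2-fold minimum, the search for whole-read steps, the differences between pairs of libraries and the choice of chromosome 11 were made after their results were seen.

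Chromosome 11 had the lowest p of the 20 chromosomes in the test of change in either direction, which does not compare chromosomes and was not set beforehand; of its 145 tested loci, 4 were among the 10 with the smallest p in each direction, 3 with higher values in microgravity (starts at 13063302, 62416257 and 102277617, mm9) and 1 with lower values (20045421). A hypothesis is that several lncRNA loci on this chromosome respond to microgravity. The adjusted p was 2.0e-05 for the real groups and 0.75 at the lowest in the other 9 splits of the libraries. It was 0.00868 without those 4 loci, which argues against these 4 as the whole source. The other loci of the chromosome at unadjusted p under 0.05 stayed in, so a small number of loci as the source is not excluded. In the same fry test 12 of the 20 chromosomes had an unadjusted p under 0.05. The share of loci at unadjusted p under 0.05 was 10.3% on chromosome 11 and 7.79% elsewhere, an odds ratio of 1.36 (95% interval 0.731 to 2.38; Fisher's exact test, two-sided, p = 0.269), which leaves open whether it holds more differing loci than others; chance also stays open, since 10 splits are too few to exclude it and the chromosome was picked from 20.

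The grouping by gravity gave more differences than any other split of the 6 libraries into 3 and 3, which number 10. There were 261 loci at unadjusted p under 0.05 with the real groups and at most 196 with another split, and 90 against 87 with the 2-fold minimum. Loci whose groups did not overlap numbered 450 against 358, and chromosomes called for change in either direction 5 against 3. In each of these 4 counts only 1 split, the real one, reached its value. The counts are not independent: all draw on the same loci and libraries, and the 90 loci are part of the 261. With 10 splits a share under 0.05 cannot be reached, and a difference between collection or library batches that coincides with the groups was not tested.

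Loci that differed by at least 2-fold at unadjusted p under 0.05 lay mostly at low levels, 63.3% of them in the lowest tertile of mean RPKM. The larger spread between libraries at low RPKM is a candidate explanation: with the other 9 splits, where gravity is mixed, the share was 55.8% to 69.6%, a range that includes the real one. In the lowest tertile, 20.6% of the ratios between microgravity replicates 3 and 1 fell within 0.2% of the pair's constant times a fraction of whole numbers up to 6. At shifted positions 1.95% did. The share was 8.29% to 10.1% in the other 3 pairs with whole-read steps (2.07% to 2.37% at shifted positions). In the 11 pairs without them it was 3.37% to 4.44% (2.40% to 3.64%). Each constant was chosen where the low-level ratios gathered most, so a small excess can come from that choice alone. Some values in the pairs with steps may thus rest on a handful of reads. Without the 2-fold minimum the order was reversed. Of the 261 loci at unadjusted p under 0.05, 63 were in the lowest tertile, 88 in the middle and 110 in the highest. A selection that adds a fold minimum to unadjusted p may therefore draw mainly on loci measured with the least precision, whatever their biology.

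Whole-read steps were shared among control replicate 2 and microgravity replicates 1 and 3, and between control replicate 3 and microgravity replicate 2, and were found in no other pair. Parting the former 3 libraries from the other 3 gave 105 loci at unadjusted p under 0.05, the lowest count of the 10 splits.

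It was asked whether lncRNA loci that lie together differ together. Over 158 pairs listed with the same coordinates, the correlation of the difference divided by its standard error was 0.0738 (permutation test, two-sided, p = 0.352), and over 670 pairs of separate neighbours within 100 kb it was 0.0385 (permutation test, two-sided, p = 0.322). Contrasts among libraries of 1 group gave -0.0023 to 0.124 and 0.0018 to 0.0516. No co-variation of neighbouring loci beyond that level was detectable, with 10000 permutations each over pairs that are not independent replicates.

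The median standard deviation between replicates of a group, without moderation, was 0.36 on the log2 scale in microgravity and 0.32 in control. It was higher in microgravity for 54.8% of 3299 loci. In 4 of the 10 splits, the real one included, the median ratio was at least as far from 1. The median absolute log2 difference between 2 libraries was 0.423 and 0.422 in the microgravity pairs with replicate 2, 0.386 in the pair without it, and 0.350 to 0.373 in control pairs, so part of the higher spread in microgravity rests on that library.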
